A study of Mus musculus with 10 samples.

How the data were processed

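The lateral shell and the medial shell of the nucleus accumbens of wild-type mice were each represented by 5 samples, which the labels call biological replicates. Per the labels' protocols, complementary DNA was obtained with Geo-seq, a method in which small pieces of a tissue section are cut out by laser capture and their RNA is amplified from a low input, and sequencing libraries were made with a transposase-based TruePrep kit. The labels do not say whether each sample came from its own animal, so all p-values measure the spread between these samples, which may be partly technical. How the captured pieces were placed within each region is not given in the sources used here.

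The deposited table holds TPM, transcript abundances scaled by the authors to a total of 1000000 per sample, for 20483 genes by symbol, with 1 column per sample. The submitters' processing notes name fastp 0.20.0, HISAT2 2.1.0, StringTie 1.3.4 and featureCounts 1.6.3 and the mouse build GRCm38 (mm10), without their roles or order. The gene annotation, the use of strand in counting and any filter behind the list of genes are not given in the sources used here. All 20483 symbols occur in GENCODE M21 on GRCm38, and coordinates and overlaps between genes were taken from there. TPM divides by gene length and by the sample total, so it keeps no sequencing depth: the depth of each library is unknown, no counting interval can be given, and a gene that takes a large share of a library lowers the values of all others. A value of 0 is described as listed at 0, since 20 of the 4272 genes with a mean of at least 20 TPM were listed at 0 in at least 1 library.

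Differences were tested with limma 3.58.1 in R 4.3.3 (linear model with empirical Bayes moderation and a mean-variance trend) on log2(TPM + 1), over the 15596 genes with a TPM of at least 1 in at least 5 of the 10 samples, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each log2 fold change is lateral minus medial on the log2(TPM + 1) scale, which understates the change of genes with low values. Nts and Cartpt also had exact two-sided permutation tests over all divisions of the 10 samples into groups of 5. The 42 gene lists cover striatal gradients and neuron classes, signalling, channels, guidance, other cell types of the brain and RNA quality; 41 had at least 4 tested members and were tested with camera in limma at a preset correlation between genes of 0.01. Camera with the correlation estimated from the residuals, and fry, were run beside it. Camera compares a list with all other genes tested. The figures were drawn with matplotlib.

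The model, the lists, the alternatives and the rule for genes named in the text were written before the data were examined, except where the closing section says otherwise. The rule takes Nts, Cartpt, Drd1 and Drd2. In each direction it adds the 12 genes with the largest absolute log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group and no overlap between the groups' values, leaving out symbols of the form Gm plus a number or ending in Rik, Ensembl identifiers and pseudogene symbols containing -ps. Symbols taken from sequenced clones, such as AC128672.1, have none of these forms and were kept. From each list it adds up to 4 members with the smallest p, whether or not they pass. Had no gene passed in a direction, the 5 smallest p would have been named. The text names part of these list members, and some results are not reported here. Hap1 falls outside the rule and was chosen after its values were seen, as a member of a list in which 5 genes passed. The alternatives changed the pseudocount, the filter on low values, the scaling between samples, the variance model, sample weights, a block for the replicate number and each sample in turn. The scripts were tested on simulated data over 15596 genes with the spread of these samples: genes given a true absolute log2 difference of 1, 2 or 3 were recovered in 17.6%, 68.2% and 89.4% of cases, 8 of 124 calls were unchanged genes, and no gene was called where none had been changed. All 4 shifted lists and none of the others were called. The simulation drew genes independently, so it says nothing about lists whose genes vary together.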

Results

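The nucleus accumbens is the ventral part of the striatum, and its shell is divided into a medial and a lateral region. The series asks how these subregions differ in reward processing, and its expression data compare captured tissue of the lateral shell (n = 5 libraries) with that of the medial shell (n = 5 libraries) in wild-type mice. Each library listed between 15402 and 17003 genes above 0. Mitochondrially encoded genes took 23.5% to 35.3% of the TPM of a library, and the 50 most abundant genes took 48.6% to 62.6%. Genes of at least 1 TPM numbered 14909 ± 507 (SD, n = 5) in lateral and 15554 ± 303 (SD, n = 5) in medial libraries (exact two-sided permutation p = 0.0397, adjusted p = 0.286 over 9 library measures). Rank correlations across genes, which are not independent replicates, ran from 0.789 to 0.858 within lateral, from 0.823 to 0.852 within medial and from 0.755 to 0.839 between the regions. The first principal component held 20.8% of the variance and separated the groups.

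The lateral shell had higher levels of 60 genes and the medial shell of 171. Stard5, a lipid-transfer protein gene, was at 71.1 ± 34.9 TPM (SD, n = 5) in medial and 1.68 ± 1.62 TPM (SD, n = 5) in lateral libraries, a log2 fold change of -4.87 with a standard error of 0.41 (limma adjusted p = 0.0003). Nrgn, encoding the calmodulin-binding postsynaptic protein neurogranin, stood at 128 ± 49.3 TPM in lateral and 7.26 ± 4.95 TPM in medial libraries (log2 fold change 4.11, standard error 0.43, limma adjusted p = 0.00112). The values of the regions did not overlap for 57 of the 60 and 151 of the 171 genes, and over all genes tested 4.25% did not overlap where chance gives 0.794%. At an unadjusted p under 0.05 there were 2399 genes, against 780 by chance. The median log2 fold change of all tested genes was -0.21, so lateral values were lower for most genes at this scaling. The share of calls on the medial side was 74% and depended on the scaling. Median-ratio scaling gave 88 genes higher in lateral and 82 higher in medial (48.2% medial). Quantile normalization gave 86 and 100 (53.8% medial). AY036118 was near 0 in lateral replicate 5 and medial replicate 2. In alternatives added after seeing the data, leaving out both libraries left 15 and 38 genes, and a term for that split gave 53 and 141. Without both libraries, in a fit of fewer samples, 31 of 50 named genes that had passed no longer did (adjusted p up to 0.178), while their log2 fold changes were 0.884 to 1.12 times those with all libraries. The other 19 were Stard5, Nrgn, Cartpt, Rgs4, Htr2a, Htr1b, Gpr101, Fgf3, Bst2, Pcp4, Slc25a18, Kcnip1, Stra6, Cxcl13, Glt8d2, Dnah7a, Hcrtr2, Wnt7a and Efna5.

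**Figure D1:**
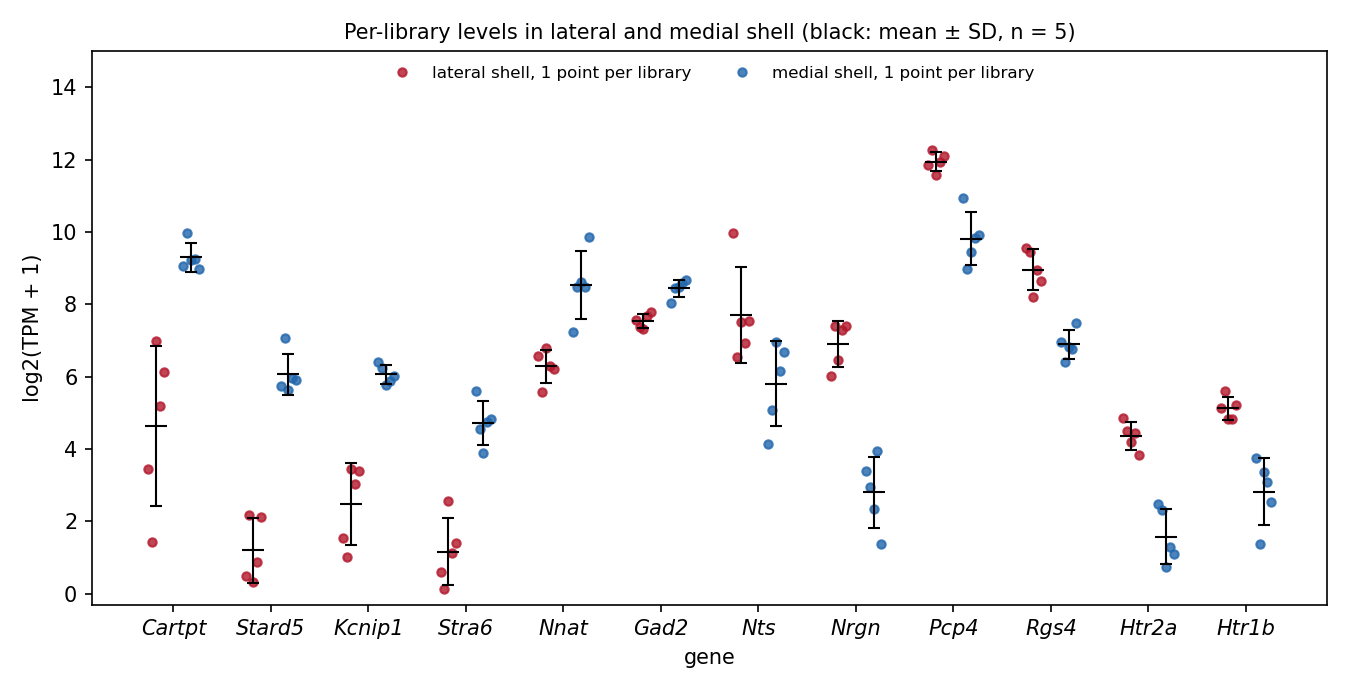
The vertical axis is log2(TPM + 1) and each coloured point is a library, red for the lateral and blue for the medial shell, with the black bars giving the mean ± SD (n = 5). Cartpt, Stard5, Kcnip1, Stra6, Nnat and Gad2 are higher in every medial than in any lateral library, Nrgn, Pcp4, Rgs4, Htr2a and Htr1b are the reverse, and the Nts points of the regions overlap.

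The neuropeptide genes Cartpt and Nts are those that the study's published work picks out for the medial and the lateral shell, so their direction here is not independent evidence. Cartpt, encoding the precursor of the CART peptides (chromosome 13, 99898489 to 99901091, minus strand, GRCm38), was at 649 ± 202 TPM (SD, n = 5) in medial and 48.4 ± 50.4 TPM (SD, n = 5) in lateral libraries. Its log2 fold change was -4.66 (standard error 0.79, limma adjusted p = 0.013), and the exact permutation p was 0.00794, the smallest that this design can give (0.0159 adjusted over both genes). Nts, encoding the precursor of neurotensin (chromosome 10, 102481756 to 102490486, minus strand), was at 315 ± 382 TPM in lateral and 69.0 ± 45.0 TPM in medial libraries. Values overlapped, at 91.7 to 996 TPM against 16.5 to 124 TPM. Its log2 fold change of 1.90 (95% interval 0.55 to 3.24) did not pass over all genes (limma adjusted p = 0.168), while the exact permutation p was 0.0397 (0.0397 adjusted over both genes). Without lateral replicate 1, the library at 996 TPM, the log2 fold change of Nts was 1.33 (adjusted p = 0.254). Adjusted over the list alone, Nts had a p of 0.0219 among the 21 tested neuropeptide genes, of which 5 on each side passed that way. Over all genes 2 passed, Cartpt and Scg2, encoding the granin secretogranin II (618 against 325 TPM, log2 fold change -0.96, adjusted p = 0.0252). Camera did not call the list (adjusted p = 0.105), except without medial replicate 5 (0.0236). Scg2 lost its call without lateral replicate 4 or any of medial replicates 2 to 5 (adjusted p up to 0.0711), under median-ratio scaling (0.0973), without a mean-variance trend (0.087) and after rescaling without mitochondrial and haemoglobin genes (0.0504).

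The dopamine receptor genes that divide the spiny projection neurons, the main neurons of the striatum, did not differ detectably. Drd1 was at 118 ± 27.7 TPM in lateral and 112 ± 27.5 TPM in medial libraries (log2 fold change 0.06, 95% interval -0.39 to 0.52, limma adjusted p = 0.915), and Drd2 at 121 ± 55.8 and 109 ± 44.1 TPM (0.10, -0.67 to 0.88, adjusted p = 0.919). Lists of D1 neuron genes (adjusted p = 0.47), D2 neuron genes (0.481) and genes shared by both (0.0998) were not called by camera. The shared list was called towards lateral without lateral replicate 1 (0.0359) or medial replicate 1 (0.0401), under median-ratio scaling (0.0275) and with sample weights (0.0475). Of the 20 shared genes 3 passed. Rgs4, a regulator of G-protein signalling, was higher in lateral (526 against 121 TPM, log2 fold change 2.07, adjusted p = 0.00244). Gad2, a GABA-synthesizing enzyme, and the retinoic acid receptor gene Rarb were higher in medial (-0.90, adjusted p = 0.0133, and -1.06, adjusted p = 0.0344). Among the D1 genes Lypd1 passed (-1.43, adjusted p = 0.013) and among the D2 genes Upb1, both higher in medial. Rarb lost its call without any of 8 of the 10 libraries, lateral replicates 1, 3, 4 and 5 and medial replicates 2 to 5 (adjusted p up to 0.0991), and under median-ratio scaling (0.0576). Without a mean-variance trend neither Rarb (adjusted p = 0.0866) nor Gad2 (0.0649) passed.

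At the preset correlation, genes described as high in ventromedial striatum were called as a list towards the medial shell, and those described as high in dorsolateral striatum towards the lateral shell. Of 14 tested genes of the ventromedial list, 13 had lower lateral values and 5 passed, Stard5, Cartpt, Nnat, Lypd1 and Hap1, with a list median of -1.40 (camera adjusted p = 1.34e-07; adjusted p = 0.0684 with an estimated correlation). The imprinted gene Nnat was at 434 ± 290 TPM in medial and 79.9 ± 23.4 TPM in lateral libraries. Adjusted over the list alone, 8 genes passed. Of 10 tested genes of the dorsolateral list, 9 had higher lateral values with a median of 0.98 (camera adjusted p = 5.6e-06; adjusted p = 0.113 with an estimated correlation). That median was 0.49 with a pseudocount of 5 and 0.60 without medial replicate 2. None passed over all genes and 4 passed adjusted over the list alone. Among the 10 were Calb1, encoding the calcium-binding protein calbindin (120 against 44.1 TPM, adjusted p = 0.109), and Coch (20.6 against 5.38 TPM, adjusted p = 0.143). Cartpt, which the study picked out, is a member of the ventromedial list. Hap1 was chosen after its values were seen and lost its call without lateral replicate 2 or medial replicates 2, 3 or 5 (adjusted p up to 0.0711) or without a mean-variance trend (0.0542). Calb1 passed without medial replicate 1 (adjusted p = 0.0329).

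The other genes with the largest differences towards the lateral shell included serotonin receptor genes. The serotonin receptor gene Htr2a was at 20.2 ± 5.47 TPM in lateral and 2.36 ± 1.78 TPM in medial libraries (log2 fold change 2.78, limma adjusted p = 0.00342), and Htr1b at 34.6 ± 8.33 and 7.12 ± 4.15 TPM (2.30, adjusted p = 0.013). They were the only 2 of 9 tested serotonin receptor genes to pass. Adjusted over the list alone, 3 passed in the lateral and 1 in the medial direction. Camera called the list (adjusted p = 0.00659, and 0.104 with an estimated correlation), although 5 members had higher and 4 lower lateral values. Its median was 0.17, and it was -0.0345 with a pseudocount of 0.1 and 1.29 with a filter of 5 TPM. Without a filter on low values that list lost its call (adjusted p = 0.0563). Dmkn had a log2 fold change of 5.15 and Atp6ap1l of 3.49. The orphan receptor gene Gpr101 (3.47), the fibroblast growth factor gene Fgf3 (3.41), the long noncoding RNA gene AC128672.1 (3.33), the insulin-like growth factor binding protein gene Igfbp6 (3.09), Rapsn (2.60), the antiviral gene Bst2 (2.53) and Ddit4l (2.31) completed the 12 selected of 53 that qualified. Their adjusted p ran from 0.00112 to 0.0325. Fgf3 and Gpr101 were listed at 0 in 4 of 5 medial libraries. With a pseudocount of 0.1 and of 5 the log2 fold change was 6.31 and 1.66 for Gpr101, 6.24 and 1.62 for Fgf3 and 5.74 and 1.89 for Atp6ap1l. It was 5.36 and 1.89 for AC128672.1, 4.02 and 1.35 for Bst2 and 5.14 and 1.15 for Rapsn. For Htr2a a pseudocount of 5 gave 1.78. With a pseudocount of 0.1 the calls of AC128672.1 (adjusted p = 0.0521), Bst2 (0.0913) and Igfbp6 (0.137) were lost. Bst2 also lost its call without lateral replicate 1, 2 or 4 or medial replicate 3, 4 or 5 (adjusted p up to 0.0654). Igfbp6 lost it without any lateral replicate or medial replicate 2, 3 or 4 (up to 0.0778). The Igfbp6 call also ended without a filter on low values (0.0519), without a mean-variance trend (0.0700) and after rescaling over nuclear protein-coding genes (0.0572). Rapsn lost it without lateral replicate 1, 2 or 4 or medial replicates 2 to 5 (up to 0.0681). Htr1b and Rapsn have antisense genes whose reads cannot be told apart if strand was not used.

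The list headed calcium-binding proteins was also called towards the lateral shell at the preset correlation. It holds calmodulin-linked genes as well, among them Nrgn, Pcp4, Camk2a and Camk4, so it is not a list of calcium-binding proteins alone. Of its 15 tested genes 9 had higher lateral values. Over all genes 2 passed, Nrgn and Pcp4 (3995 ± 713 against 1004 ± 564 TPM, log2 fold change 2.13, adjusted p = 0.00368), and 4 passed adjusted over the list alone. Camera called the list (adjusted p = 2.09e-05; adjusted p = 0.0684 with an estimated correlation), whose median was 0.35. The median was 0.21 without lateral replicate 2, 0.17 without medial replicate 3 and 0.56 under median-ratio scaling. Towards the medial shell, after Stard5 and Cartpt, the 12 selected of 116 that qualified were the mitochondrial carrier gene Slc25a18 (-3.78), Kcnip1, encoding a subunit partner of A-type potassium channels (-3.58), the retinol transporter gene Stra6 (-3.57), the chemokine gene Cxcl13, Glt8d2 (-3.25), Upb1 (-3.09), Samd8 (-2.84), Rasd1 (-2.74), Dnah7a (-2.72) and Tmem255a (-2.63), with adjusted p from 0.0003 to 0.0152. Kcnip1 was at 66.7 ± 12.1 TPM in medial and 5.91 ± 4.21 TPM in lateral libraries. Cxcl13 was listed at 0 in all 5 lateral libraries and at 6.2 to 16.2 TPM in the medial ones (adjusted p = 0.00112). With a pseudocount of 0.1 and of 5 the log2 fold change was -5.34 and -1.74 for Glt8d2, -5.32 and -1.20 for Dnah7a and -4.42 and -1.41 for Rasd1, whose call was lost at 0.1 (adjusted p = 0.0555). A pseudocount of 5 gave -2.25 for Stra6, -1.90 for Upb1 and -1.67 for Samd8. Tmem255a lost its call without medial replicate 2 (adjusted p = 0.0509). Stard5 overlaps Gm45838 on its strand and Il16 on the other, and Slc25a18, Glt8d2 and Tmem255a overlap antisense genes.

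**Figure D2:**
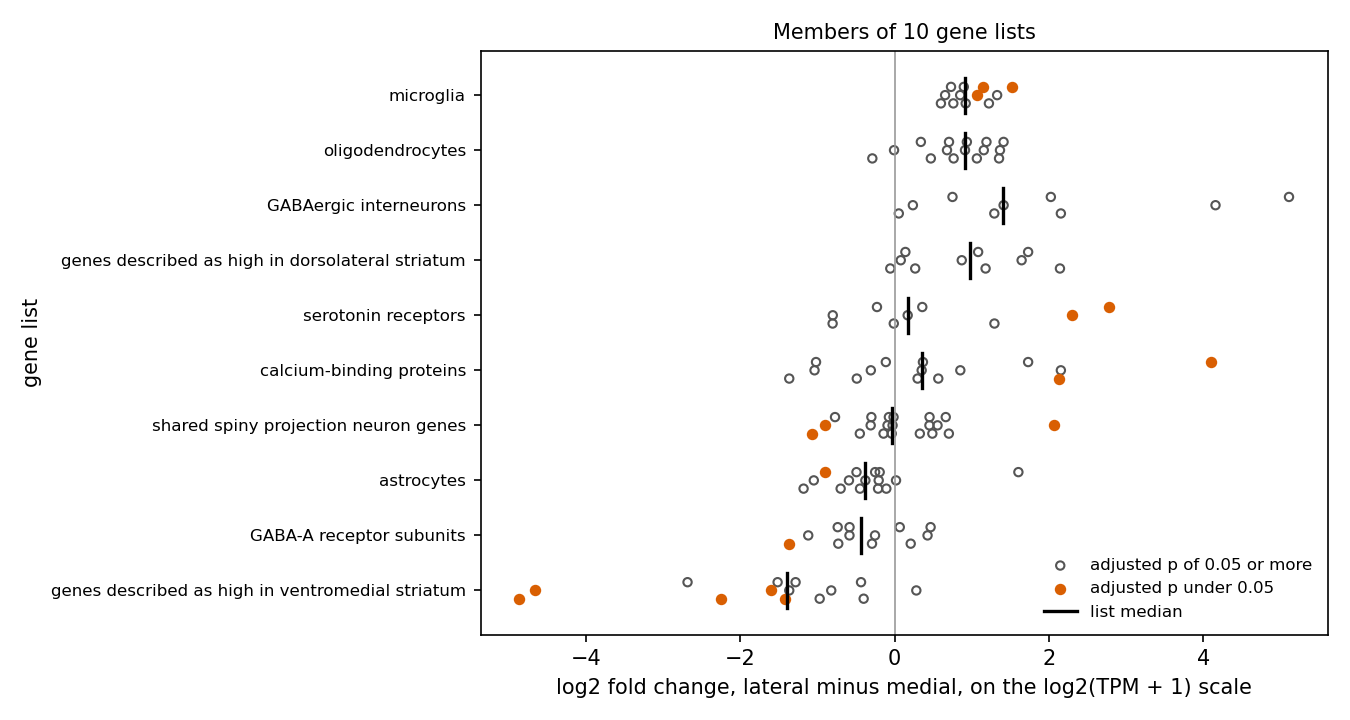
The horizontal axis is the log2 fold change, lateral minus medial, on the log2(TPM + 1) scale, for the tested members of 10 gene lists, 1 circle per gene, filled where the limma adjusted p was under 0.05, with a black line at the list median. All 12 microglia genes lie to the right of 0 and 13 of 14 ventromedial genes to the left.

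Lists of microglia and oligodendrocyte genes were called towards the lateral shell at the preset correlation, and neither with an estimated one. All 12 microglia genes had higher lateral values (median 0.91, camera adjusted p = 4.17e-15; adjusted p = 0.0684 with an estimated correlation). Over all genes 3 passed, C1qa, a complement component (106 ± 15.9 against 52.3 ± 19.8 TPM), Tmem119 (21.2 against 7.10 TPM) and Ctss (88.6 against 40.2 TPM), and 10 passed adjusted over the list alone. C1qa and Tmem119 lost their calls without any lateral replicate or medial replicate 2, 4 or 5 (adjusted p up to 0.0989 and 0.102). Ctss did so without the same libraries except lateral replicate 3 (up to 0.103). Without a mean-variance trend none of the 3 passed (adjusted p = 0.0958, 0.0638 and 0.0998). Tmem119 and Ctss did not pass with a pseudocount of 0.1 (0.053 and 0.0526) or without a filter on low values (0.0574 and 0.055), nor Ctss with the AY036118 term (0.0538). Of 15 oligodendrocyte genes, 13 had higher lateral values (median 0.91, camera adjusted p = 1.34e-07; adjusted p = 0.412 with an estimated correlation). The median was 0.47 without medial replicate 2 and 0.38 without that library and lateral replicate 5. None passed over all genes and 2 passed adjusted over the list alone. Mobp, a myelin gene, was at 89.0 ± 52.1 against 30.0 ± 6.33 TPM (adjusted p = 0.0691, and 0.0443 without lateral replicate 3) and Mbp at 95.3 ± 57.9 against 34.0 ± 14.7 TPM (adjusted p = 0.141). Of 15 astrocyte genes 13 had lower lateral values and 1 passed, the neurotensin receptor gene Ntsr2 (26.5 against 50.1 TPM, adjusted p = 0.0492). The gap junction gene Gja1 was at 48.9 against 93.3 TPM (adjusted p = 0.128). Ntsr2 lost its call in 9 of 10 fits without a single library, the exception being lateral replicate 2, with an adjusted p of up to 0.113. It also lost it with a pseudocount of 0.1 (0.0582), without the filter (0.0605), under quantile normalization (0.0747) and under median-ratio scaling (0.091). Variance models without the trend (0.11), with robust fitting (0.0514) or with sample weights (0.0541) ended it too. Camera did not call the astrocyte list (adjusted p = 0.114), except towards medial without lateral replicate 1 (0.00595).

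GABAergic interneuron genes were called towards the lateral shell as a list, with all 9 tested members positive (median 1.41, camera adjusted p = 5.34e-07; adjusted p = 0.113 with an estimated correlation). With a pseudocount of 0.1 the median was 2.32. No member passed over all genes, and 4 passed adjusted over the list alone. Somatostatin, Sst, was at 1146 ± 921 TPM in lateral and 191 ± 357 TPM in medial libraries (adjusted p = 0.089), and neuropeptide Y, Npy, at 1258 ± 1047 and 200 ± 343 TPM (adjusted p = 0.0834). Both passed without medial replicate 5, at 825 TPM of Sst (adjusted p = 0.0208 for each). Cholinergic interneuron genes were not called as a list (camera adjusted p = 0.0998, and 0.713 with an estimated correlation). They were called towards lateral without lateral replicate 4 (0.0119) or 5 (0.0187) or medial replicate 4 (0.013) or 5 (0.02). The median of the list was 0.203. Over 24 alternatives it ran from -0.472 to 0.783, with the other sign in 6.

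Other lists held passing members on both sides. In the retinoic acid, Wnt and growth factor list (adjusted p = 0.939), genes higher in medial included Stra6, Wnt7a (-2.07, adjusted p = 0.00541) and Rarb, and 2 of 31 were higher in lateral, Igfbp6 and Igfbp5 (1.32, adjusted p = 0.0323). Among 41 axon guidance genes (adjusted p = 0.572), Efna5 (-2.29), Nrp1 (-1.87) and Efnb2 (-1.13) were higher in medial and Plxnd1 (2.26) in lateral. Among 21 neuropeptide receptors (adjusted p = 0.501), the orexin receptor gene Hcrtr2 (-2.53, adjusted p = 0.013) and Ntsr2 were higher in medial and Gpr101 in lateral. Camera called neither the GABA-A receptor subunits (adjusted p = 0.114) nor the sodium, calcium and HCN channels (adjusted p = 0.0926), though the channels were called towards lateral without lateral replicate 1 (0.0352) or medial replicate 1 (0.0218). Ddc, which makes dopamine and serotonin from their precursors, was the only 1 of 20 dopamine signalling genes to pass and was higher in medial (-2.24, adjusted p = 0.013). Camera called that list towards lateral (adjusted p = 0.0088, and 0.578 with an estimated correlation), although 12 members had higher and 8 lower lateral values. Its median was 0.087, and it was -0.022 without lateral replicate 2 and 0.297 under median-ratio scaling. The call was lost without lateral replicate 2 (adjusted p = 0.0561) or medial replicate 3 (0.0921) and under quantile normalization (0.0899). Cadherin genes passed in each direction, Cdh2 (-1.33) and Cdh13 (1.55). Single genes passed among potassium channel genes (Kcnip1), immediate early genes (Egr3, 1.18), endocannabinoid genes (Mgll, -0.74), regional transcription factors (Rarb), striosome genes (Lypd1), subventricular progenitors and neuroblasts (Sox11, -1.47), septal and subcortical neurons (Hcrtr2) and islands of Calleja cells (Rreb1, -2.31). Camera adjusted p of those lists ran from 0.0648 to 0.716, except the islands of Calleja list, too short to test. Adjusted over the list alone, 1 immediate early gene passed towards lateral and 4 towards medial. Potassium channels were called towards lateral without medial replicate 1 (0.0297), regional transcription factors likewise without a mean-variance trend (0.0421), and the subventricular list towards medial without lateral replicate 3 (0.0491). Calls were also lost without single libraries, with an adjusted p of up to 0.0834. For Igfbp5 these were lateral replicates 2 to 5 and medial replicates 2 to 4. For Egr3 they were lateral replicates 2 and 5 and medial replicate 2, and for Efnb2 medial replicates 2 and 5. Plxnd1 depended on lateral replicates 1, 2, 3 and 5 and medial replicates 2, 3 and 5. Cdh2 depended on lateral replicate 4 and medial replicates 2 to 5, and Cdh13 on lateral replicates 1, 2 and 5 and medial replicates 2 and 3. Mgll depended on lateral replicates 1, 4 and 5 and medial replicates 2 to 5, and Sox11 on lateral replicates 1 and 2 and the same medial ones. Rreb1 depended on lateral replicates 4 and 5 and medial replicates 1, 2, 4 and 5. Median-ratio scaling ended the calls of Mgll (0.0954), Sox11 (0.0614) and Rreb1 (0.0503), and quantile normalization those of Mgll (0.0577) and Sox11 (0.0661). Without the trend Mgll (0.0976), Sox11 (0.0638) and Cdh13 (0.0518) did not pass. A pseudocount of 0.1 ended the calls of Plxnd1 (0.0538) and Rreb1 (0.0703). Igfbp5 did not pass without the filter (0.0519), nor Mgll after rescaling over nuclear protein-coding genes (0.0511). The log2 fold change of Hcrtr2 was -4.59 with a pseudocount of 0.1 and -1.12 with 5. A pseudocount of 5 gave 0.86 for Igfbp5, -1.23 for Nrp1, 1.38 for Plxnd1 and -1.43 for Rreb1.

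The mitochondrially encoded genes (median 0.14, adjusted p = 0.00346; adjusted p = 0.453 with an estimated correlation), ribosomal protein genes (median 0.00, adjusted p = 0.0489; adjusted p = 0.789) and endothelial genes (median 0.20, adjusted p = 0.0499; adjusted p = 0.598) were also called towards lateral, without a passing member. The mitochondrial list lost its call under quantile normalization, where its direction turned (median -0.018, adjusted p = 0.875). Its median was 0.075 without lateral replicate 3, 0.061 without medial replicate 4 and 0.35 under median-ratio scaling. The endothelial call was lost in 10 of 24 alternatives, among them those without lateral replicate 1, 2 or 3 or medial replicate 1 or 4 (adjusted p up to 0.158). The endothelial median was 0.036, 0.051, 0.30 and 0.37 without lateral replicates 1, 2, 4 and 5 and 0.090 without medial replicate 1. It was 0.34 without lateral replicate 5 and medial replicate 2, 0.34 under quantile normalization and 0.41 under median-ratio scaling. The ribosomal call was lost in 6, those without lateral replicate 5 or medial replicate 1 or 4 (up to 0.678), without the filter (0.0847), under quantile normalization (0.201) and without lateral replicate 5 and medial replicate 2 together (0.566). The ribosomal median, near 0, ran from -0.095 without lateral replicate 5 to 0.21 under median-ratio scaling. No gene passed among adrenergic, muscarinic and nicotinic receptors (adjusted p = 0.0624), ionotropic glutamate receptors (0.633), metabotropic glutamate and GABA-B receptors (0.734), oligodendrocyte precursors (0.939), mural and leptomeningeal cells (0.123), ependymal and choroid plexus cells (0.408), cortical and claustral excitatory neurons (0.367), haemoglobin genes (0.0738), nuclear oxidative phosphorylation genes (0.123), heat shock and stress genes (0.951) and sex-linked genes (0.0998). Of these lists, 4 were called towards lateral in some alternatives. For the adrenergic, muscarinic and nicotinic receptors these were the fits without lateral replicate 3 (0.0491) or 4 (0.0408) or medial replicate 3 (0.0274) or 5 (0.033), with a pseudocount of 0.1 (0.0436) and with a filter of 5 TPM (0.00166). Mural and leptomeningeal genes were called without lateral replicate 3 (0.0313) or medial replicate 3 (0.0143). Haemoglobin genes were called without lateral replicate 2 (0.00257) or medial replicate 1 (0.0113) or 4 (0.0106). Nuclear oxidative phosphorylation genes were called without medial replicate 5 (0.0122), under median-ratio scaling (3.5e-05), after rescaling without mitochondrial and haemoglobin genes (0.0269) and over nuclear protein-coding genes (0.0396). Of the 41 lists tested, 11 passed with the preset correlation, none with an estimated correlation and 9 by fry, 4 of them among the 11. Called by fry alone were sex-linked genes (fry adjusted p = 0.0302), GABA-A receptor subunits and the retinoic acid, Wnt and growth factor list (0.0358 each). The subventricular and the septal and subcortical lists (0.0358 each) were the others. All had medians below 0. Fry, unlike camera, does not compare a list with other genes, and the median of all tested genes was -0.207.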

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

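All tests of explanations in this part were chosen after the results were seen.

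A sample stood far from the other 4 of its group in 13 of 138 groups of 5 values. Chance gives about 7 for normally distributed values, which groups with 4 values listed at 0 are not. The gap to the nearest library, as a share of the group's range on the log2(TPM + 1) scale, was 0.716 for Cartpt in medial replicate 2 (highest) and 0.777 for Stard5 in that library (highest). It was 0.712 for Dmkn in medial replicate 1 (27.9 against at most 1.63 TPM) and 1 for Rapsn in the same library, whose other medial values were listed at 0. In medial replicate 1 it was also 0.844 for Samd8 (lowest, 2.7 TPM) and 0.728 for Tmem255a (lowest, 8.58 TPM). Values listed at 0 in the other 4 libraries gave 1 for Dnah7a in lateral replicate 1, Fgf3 in medial replicate 4 and Gpr101 in medial replicate 3. It was 0.72 for Egr3 in medial replicate 3 (lowest) and 0.726 for Plxnd1 in lateral replicate 4 (lowest). For library measures the gap was taken on the percentages, without a log. The share of TPM in genes resembling mitochondrial sequence was lowest in medial replicate 4 (6.87%, gap 0.928), and CT010467.1 took 10.1% of lateral replicate 5 (gap 0.749).

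Microglia and oligodendrocyte lists were called towards the lateral shell, but neither call held with an estimated correlation (camera adjusted p = 0.0684 and adjusted p = 0.412), no oligodendrocyte gene passed over all genes, and the mean oligodendrocyte level per library did not pass (exact permutation p = 0.206). A lower share of neurons would raise all other cell types alike. The mean microglia level minus the mean astrocyte level differed by 1.31 on the log2 scale between regions, with all 5 lateral libraries above all medial ones (exact permutation p = 0.00794, 0.0556 adjusted over 14 scores). Against endothelial markers the difference was 0.79, with only 1 lateral library above all medial ones (exact permutation p = 0.0714, adjusted 0.2). Neither difference passed after adjustment, and the astrocyte comparison was chosen after the lower lateral astrocyte values were seen. A lower share of neurons is therefore left undecided as a cause for microglia. For oligodendrocytes the difference from astrocytes was 1.14 (exact permutation p = 0.0556), so a lower share of neurons cannot be told apart there, because the groups overlap. A lower share would also lower neuron genes. The mean level of the shared spiny projection neuron genes was 7.39 ± 0.215 in lateral and 7.31 ± 0.23 in medial libraries (SD, exact permutation p = 0.603). No loss of these genes was seen, although a small loss cannot be excluded. The microglia and oligodendrocyte patterns remained under 4 other scalings, with lowest list medians of 0.99 and 1.03. Each of those scalings moved the median of all genes upwards, from -0.207 to between -0.152 and -0.00101. Lower list medians were therefore not to be expected, so these fits cannot decide whether scaling contributes. The oligodendrocyte median was 0.38 without lateral replicate 5 and medial replicate 2 (0.91 with all libraries). More microglia or myelin in the captured lateral pieces, whether by region or by where the pieces were cut, stays open and untested.

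Nrgn, Pcp4, Rgs4 and Htr2a, higher in the lateral shell, are also abundant in cortical neurons, so cortical or claustral cells in the lateral pieces are a candidate source. The mean level of 8 markers of such neurons differed by 0.13 on the log2 scale (exact permutation p = 0.143). In lateral libraries Neurod6, Nrn1, Nr4a2 and Fezf2 reached at most 3.31, 0.809, 0.469 and 1.49 TPM, which goes against a large share of such cells. Nptx1 was at 5.71 to 12.4 TPM in lateral and 0.415 to 5.98 TPM in medial libraries. The highest value of Rorb was larger in lateral libraries (10.6 against 7.55 TPM), but came from lateral replicate 1, which also held the highest Neurod6. In the other lateral libraries Rorb ran from 3.11 to 6.30 TPM, against 5.26 to 7.55 TPM in medial ones. The highest values of Cux2 and Lmo3 were not larger in lateral libraries (5.87 against 6.54 and 53.8 against 75.2 TPM). Lmo3, the only marker above 20 TPM, is also expressed by the striatum. A smaller share and a difference between striatal neurons cannot be told apart, since no cortical levels were used here to set the share that each gene would need. A difference between the neurons of the regions was not tested.

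Sst and Npy had higher lateral means with a large spread, but neither passed (limma adjusted p = 0.089 and 0.0834), the values of the regions overlapped, and the GABAergic list was not called with an estimated correlation (adjusted p = 0.113). Few such cells per captured piece, in numbers that vary between libraries, is a candidate for the spread. Across the 10 libraries, as deviations from group means, Sst and Npy moved together (Pearson r = 0.919, permutation p = 0.0013, adjusted 0.002). Spearman rho was 0.903 (permutation p = 0.0044, adjusted 0.0081), and Pearson r was 0.826 without the 2 libraries farthest from the median. Any cause that varies these cells together would give such a correlation, so it cannot single out few cells per piece. It was taken within groups, so it does not bear on the difference between regions. Sst also moved with Chat, a gene of cholinergic cells (Pearson r = 0.743, permutation p = 0.024, adjusted 0.024; Spearman rho = 0.733, p = 0.046, adjusted 0.046; r = 0.583 without the 2 libraries farthest from the median), so a property of the piece shared by both cell types stays open. These were 2 of 3 relations computed. A regional difference in the number of Sst and Npy cells stays open.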

How the results depend on the processing

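The rescaling over nuclear protein-coding genes, the omission of 2 libraries and the term for AY036118 were chosen, and the bounds for the divisions of the samples written down, after seeing the data. Chance alone is unlikely for the gene counts, if the samples are independent, which the labels do not state. Among 100 divisions of the samples into groups of 5, the real one included, only 1 gave as many genes in its larger direction (171, highest other 5). Only 1 gave as many in its smaller direction (60, highest other 1). Chance stays open for the number of lists, since 16 divisions gave at least 11 (highest other 16). Higher in lateral, 60 genes became 34 without a mean-variance trend and 15 without lateral 5 and medial 2; the cause was not tested, beyond the fewer samples of the last. Higher in medial, 171 became 107 with a pseudocount of 0.1, 100 under quantile normalization, 82 under median-ratio scaling, 111 without the trend and 38 in the 8 libraries; scaling moves the median of all genes to -0.00101 and -0.0246, and otherwise the cause was not tested. Leaving out single libraries gave 23 to 69, 56 to 188 and 10 to 15 lists, with fewer samples in each fit. The 11 lists became 7 under quantile normalization and 0 with an estimated correlation; the cause was not tested. A replicate block gave 19 and 45 genes and 12 lists. Named genes whose calls it ended included Htr1b (limma adjusted p = 0.0598), C1qa (0.0598) and Nrp1 (0.0707). Same-numbered libraries did not deviate together (correlations of same-numbered deviations -0.0534 to 0.0417, of other-numbered ones -0.108 to 0.13). Of 5 lateral libraries 0 correlated best with their own number. The labels do not say whether equal numbers mark the same animal, and these correlations cannot exclude it. Cartpt passed in all 24 alternatives (log2 fold change -5.24 to -3.86) and Nts in none (1.33 to 2.19, adjusted p 0.124 to 0.408). Drd1 turned without lateral replicate 1 (-0.00506) or 2 (-0.0122) and medial replicate 3 (-0.0261) or 4 (-0.000938; range without single libraries -0.0261 to 0.211), and Drd2 without lateral replicate 2 (-0.119) or medial replicate 3 (-0.126; range without single libraries -0.126 to 0.404), all far from the threshold. Of 50 named genes that passed, 26 kept their call in all 10 fits without a single library, 4 more in the 5 of those fits that tested them, and 17 in all alternatives that tested them. For those 4 (Atp6ap1l, Cxcl13, Fgf3 and Gpr101) the 5 fits left out only libraries of the lower group. The filter dropped these genes when a library of the higher group was left out, so their dependence on single libraries of that group was not tested. Depth is unknown, so precision of low values cannot be given.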

Other observations

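The tests on how cholinergic genes vary together in this part were chosen after the result was seen.

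Eif2s3y, a Y-linked gene, was above 0 in all 10 libraries, at 15.6 ± 3.91 TPM in lateral and 28.8 ± 6.61 TPM in medial libraries (adjusted p = 0.102). AY036118 was at 8.25% to 14.4% of TPM in 8 libraries and near 0 in lateral replicate 5 and medial replicate 2, where CT010467.1 took 10.1% and 9.43% against 1.85% to 4.31% elsewhere. The cause was not tested.

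The cholinergic interneuron list was not called with all libraries (camera adjusted p = 0.0998, and 0.713 with an estimated correlation). It was called towards lateral in 4 of 24 alternatives, those without lateral replicate 4 or 5 or medial replicate 4 or 5 (lowest adjusted p 0.0119). In 6 of the 24 its median had the other sign (lowest -0.472, against 0.203 with all libraries). Its 8 tested genes varied together between libraries of a region. The mean pairwise correlation of their deviations from group means was 0.94, where 10000 random lists of equal size matched on mean expression gave at most 0.431 (median 0.0174). Among them Chat and Slc5a7 moved together (Pearson r = 0.986, permutation p = 0.00045, adjusted 0.0014; Spearman rho = 0.867, p = 0.0054, adjusted 0.0081; r = 0.996 without the 2 libraries farthest from the median; 1 of 3 relations computed). The cause was not tested.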
